A study of Mus musculus with 16 samples.

How the data were processed

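The study measured total RNA by random-primed RNA sequencing of frozen and thawed mouse PBMCs, prepared from EDTA blood by Ficoll and red cell lysis, per the labels. The authors processed the reads with bcl2fastq, Trim Galore, HISAT2 and featureCounts, and name the genome builds mm39 and hg38, per the labels, which give no versions and no annotation release. The deposited values are TPM for 51179 mouse gene identifiers in 16 libraries, and each library summed to the same total over all listed genes when checked. Of these genes 32629 were above 0 in at least 1 library. Gene names came from the table and, where it gave only an identifier, from GENCODE M21, which matched 48486 identifiers and was used for names and gene types alone, so that no positions are given. The low values of each gene were whole multiples of 1 step per library, from which whole read numbers were recovered within a tolerance of 0.001. The recovered number of a gene detected in few libraries can be a divisor of the true one. As a check, the gene lengths that these numbers imply were compared with annotated lengths, and their ratio lay within 1.5-fold of its median for 86.0% of tested genes. Library totals of recovered reads spanned a 5.16-fold range.

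Groups were taken from the labels: 5 chow, 5 HFD+L-NAME and 6 HFD+L-NAME+NO2-OA libraries. A linear model with 1 coefficient per group was fitted to log2(TPM + 1) of all 16 libraries with limma 3.58.1 in R 4.3.3, with a trend in the moderated variance and two-sided tests. Tested genes had at least 1 TPM in at least 5 libraries, which left 16365, of which 10900 were protein-coding. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called in each of the 3 comparisons. Group values are mean ± SD of TPM, and log2 differences are given with the standard error of the fit.

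A set of 49 gene lists, 20 of cell types and 29 of pathways, was written from general knowledge, with 659 entries for 618 genes, 41 of them in more than 1 list. The 45 lists with at least 3 tested members were compared with all other genes by limma's camera with its preset correlation of 0.01, adjusted over the lists. Beside it stand camera with an estimated correlation, limma's fry, and an exact two-sided permutation test of the list score, the mean over members of log2(TPM + 1). The lists of basophils and mast cells, eosinophils, haematopoietic progenitors and endothelial cells had too few tested members. The genes named are, for each comparison, up to 10 called genes with the largest rise and 10 with the largest fall, filled up to 20 with those of smallest unadjusted p as values that did not pass. Gene models named Gm or Rik, pseudogenes, immunoglobulin and T cell receptor segments and genes with a mean under 2 TPM were left out of these, and a few genes that the rule names are not reported here. Added were the 4 members with the smallest p of each list that passed, and up to 2 members of highest mean TPM of each cell type list. The tests, lists, rule for names and 12 alternatives besides leaving out each library were chosen before the data were examined.

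A further 10 alternatives were added after the data were seen: protein-coding genes alone, voom on recovered reads without and with quality weights, leaving out 3 libraries under 25% protein-coding TPM, leaving out 4 libraries with peritoneal macrophage genes, each run of library numbers alone, genes with a mean of at least 10 recovered reads, and, for the relation of log2 differences, the libraries without those genes and run 1 alone. The replicate numbers were checked for pairing: of 15 pairs of libraries with the same number, 3 had deviations from their group means correlated above 0.1, with a range from -0.51 to 0.51, so that no pairing was used. The procedure was tested on simulated data with known changes, in which genes varied independently of each other, unlike in the data. The changes were placed in genes with a mean log2(TPM + 1) of at least 1. The rates below therefore describe those simulated genes and may not hold for the real test. A log2 change of 1 was recovered for 9.0% of changed genes in HFD+L-NAME against chow, 11.9% in HFD+L-NAME+NO2-OA against HFD+L-NAME and 11.9% in HFD+L-NAME+NO2-OA against chow, and a change of 2 for 85.1%, 79.1% and 89.6%. Unchanged genes made up 8.3%, 3.1% and 6.9% of the genes called in these simulated sets, in the same order. In unchanged simulated groups, camera with an estimated correlation called a list in 12 of 100 draws. These groups kept the correlation between genes but set the mean of each gene to 0, so their variance trend was not that of the data. Tables were handled with the R package data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. The R package statmod (version 1.5.0) was installed beside limma.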

Results

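Gene expression was measured by RNA sequencing of peripheral blood mononuclear cells (PBMCs) from C57BL/6N mice in 16 libraries. Heart failure with preserved ejection fraction (HFpEF) was modelled with a high-fat diet (HFD) and L-NAME, an inhibitor of nitric oxide synthase, given for 15 weeks. The 3 groups were chow (n = 5), HFD+L-NAME (n = 5) and HFD+L-NAME with NO2-OA, nitro-oleic acid, given over the last 4 weeks (HFD+L-NAME+NO2-OA, n = 6). The labels number the libraries within each group and do not state that each comes from a different mouse, so the p-values measure differences between libraries. Expression was given as TPM, a length-scaled transcript abundance with the same total in each library, for 51179 mouse genes. Recovered reads, the whole read numbers that the steps of the TPM values imply, averaged 12.3 ± 3.05 M reads (M for 1000000, SD, n = 5) in chow, 10.3 ± 3.22 M (n = 5) in HFD+L-NAME and 13.1 ± 6.82 M (n = 6) in HFD+L-NAME+NO2-OA. They ranged from 4.94 M in HFD+L-NAME replicate 5 to 25.48 M in HFD+L-NAME+NO2-OA replicate 1. A single read of a gene of 1 kb stood for 0.0464 to 0.180 TPM.

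The cells of origin were visible in their marker genes. Cd79a, a subunit of the B cell receptor complex, averaged 429 ± 235 TPM in chow (SD, n = 5), and Lyz2, the lysozyme of monocytes and granulocytes, 1300 ± 520 TPM. The platelet chemokine Ppbp averaged 4478 ± 4164 TPM in chow, and the neutrophil calprotectin gene S100a9 averaged 444 ± 505 TPM. Haemoglobin genes took from 0.141% of all TPM in chow replicate 1 to 30.7% in HFD+L-NAME+NO2-OA replicate 1, with group means of 3.22% ± 3.22 (SD, n = 5) in chow, 4.95% ± 4.52 (n = 5) in HFD+L-NAME and 11.0% ± 11.5 (n = 6) in HFD+L-NAME+NO2-OA. Protein-coding genes together took 22.1% of TPM in chow replicate 3, 15.1% in HFD+L-NAME replicate 5 and 15.9% in HFD+L-NAME+NO2-OA replicate 2, against 39.1% to 56.4% in the other 13 libraries. Of recovered reads they took 83.4%, 79.7% and 83.9% in these 3 libraries. The other 13 ranged from 80.5% in HFD+L-NAME replicate 1 to 88.7% in HFD+L-NAME replicate 4, so the gap was in TPM, which scales reads by gene length, far more than in reads. The median correlation of log2(TPM + 1) across tested genes was 0.916 for pairs of libraries within a group and 0.919 for pairs from different groups.

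**Figure D1:**
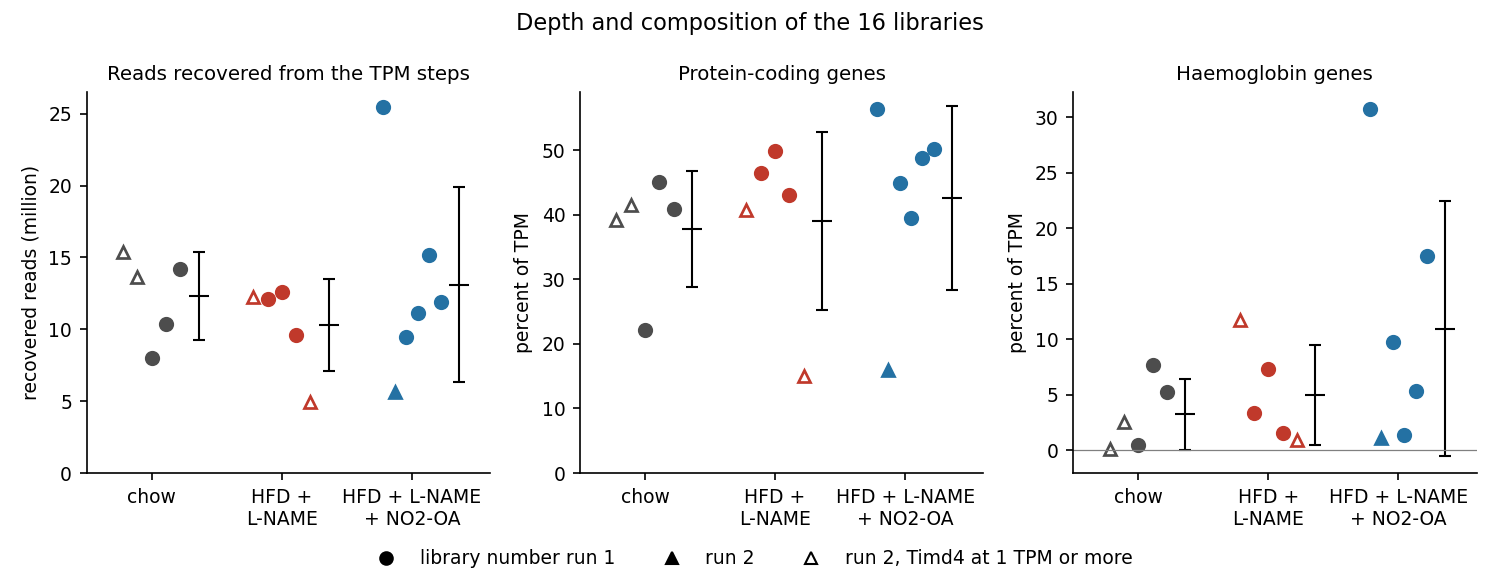
Recovered reads (axis in units of M reads), the share of TPM in protein-coding genes (percent) and the share in haemoglobin genes (percent) for each library, by group, with black marks for the mean ± SD. Triangles mark the libraries with the higher numbers in their names (run 2), and open triangles those with at least 1 TPM of Timd4; the haemoglobin share reached 30.7% in 1 NO2-OA library.

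Genes of resident peritoneal macrophages were present in 4 libraries: chow replicates 1 and 2 and HFD+L-NAME replicates 1 and 5. Alox15 (ENSMUSG00000018924), which encodes a lipoxygenase, lay between 86.0 and 175 TPM in these 4 libraries and at 1.24 TPM or less in the other 12. Prg4, which encodes lubricin, lay between 87.3 and 297 TPM in the same libraries and at 0.480 TPM or less elsewhere. The phosphatidylserine receptor Timd4 lay between 3.28 and 7.16 TPM there and was listed at 0 in the other 12, and the complement gene C1qa lay between 36.6 and 72.2 TPM there against at most 0.302 TPM. The numbers in the library names fall into 2 runs. All 4 libraries belong to the 5 of the run with higher numbers (run 2), whose other member is HFD+L-NAME+NO2-OA replicate 2. The other 11 libraries (run 1) hold 3 chow, 3 HFD+L-NAME and 5 HFD+L-NAME+NO2-OA libraries.

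**Figure D2:**
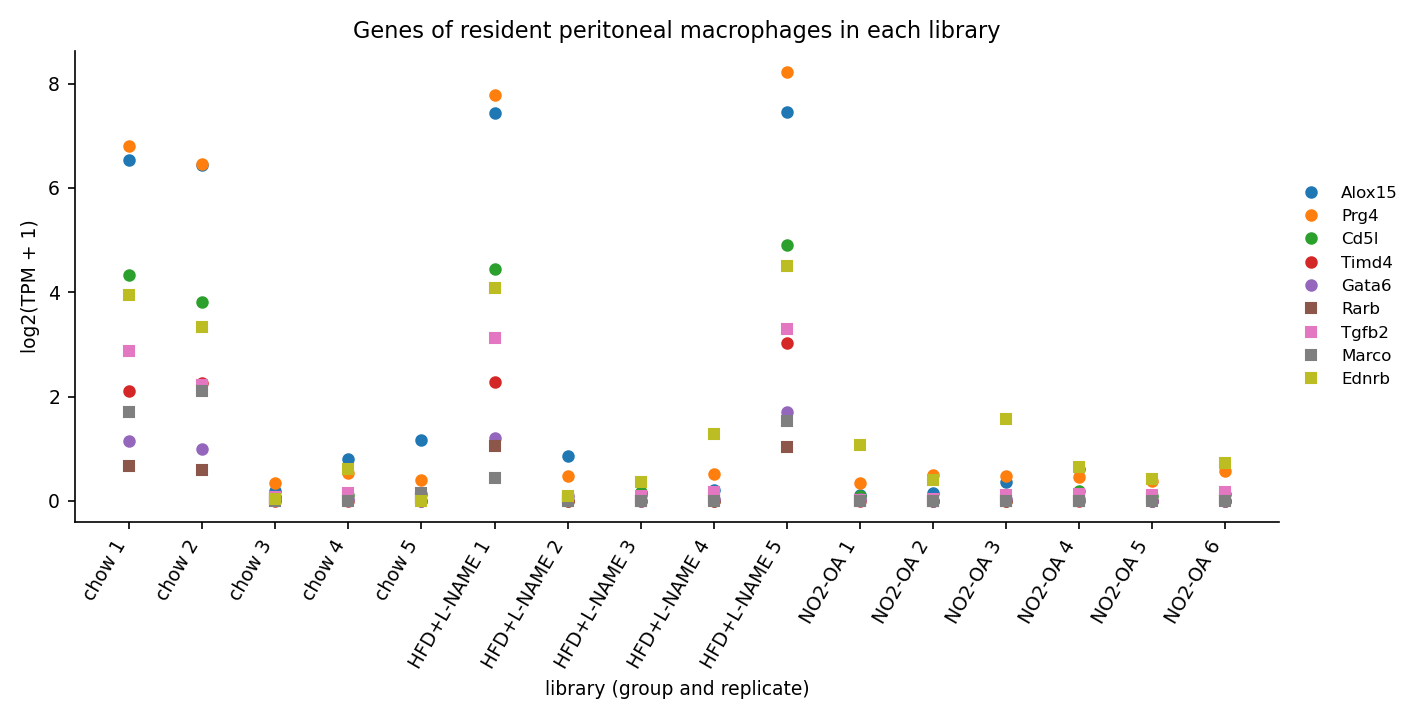
Expression of 9 genes of resident peritoneal macrophages on the log2(TPM + 1) scale in each of the 16 libraries, with circles for 5 markers chosen after their values were seen and squares for the 4 of 6 further markers, listed before their values were seen, that followed them. The 4 libraries with high values are chow 1, chow 2, HFD+L-NAME 1 and HFD+L-NAME 5; Timd4 was listed at 0 in the other 12.

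The comparison of HFD+L-NAME with chow asks how circulating cells of mice under the HFpEF-inducing regimen differ from those of control mice. T cell and NK cell genes lay lower, and granule genes of immature neutrophils higher, in HFD+L-NAME mice, although no single gene of these groups passed the test over all genes (each adjusted p = 0.817). Trac (ENSMUSG00000076928), the constant region of the T cell receptor alpha chain, averaged 46.6 ± 30.4 TPM (SD, n = 5) against 99.8 ± 40.7 TPM in chow (n = 5), a log2 difference of -1.19 ± 0.44 (SE). Gzma (ENSMUSG00000023132), a granzyme of cytotoxic cells, averaged 15.5 ± 14.4 against 42.0 ± 20.6 TPM (-1.62 ± 0.50), with 0 of 5 libraries above the chow median. Ngp (ENSMUSG00000032484), a secondary granule protein of maturing neutrophils, averaged 57.7 ± 49.4 against 11.1 ± 9.99 TPM (2.62 ± 0.73), with 5 of 5 libraries above the chow median.

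All 11 tested members of the T cell list lay below 0 in this comparison, with a mean log2 difference of -1.01, and 9 of them passed when adjusted over the list alone. The list fell by camera with its preset correlation of 0.01 (adjusted p = 3.99e-12 over 45 lists), and had an adjusted p = 0.319 with an estimated correlation. Cd3g, a subunit of the receptor complex, differed by -1.25 ± 0.39, Cd5 by -0.97 ± 0.35 and Thy1 by -1.17 ± 0.41. All 11 members of the NK cell list lay below 0 too, with a mean of -0.99, 9 past the threshold when adjusted over the list alone, and an adjusted p = 1.81e-10 (adjusted p = 0.319 with an estimated correlation). Klra4, an activating receptor of the Ly49 family, differed by -1.49 ± 0.43 and Klrd1 by -1.20 ± 0.43. The CD8 T cell list fell with a mean of -0.78 and 3 of 5 members past the threshold when adjusted over the list alone (adjusted p = 0.00103; adjusted p = 0.405 with an estimated correlation), with Cd8b1 at -1.27 ± 0.43 and Cd8a at -1.18 ± 0.43. The CD4 and naive T cell list fell with a mean of -0.85 (adjusted p = 0.000167; adjusted p = 0.405 with an estimated correlation), 0 of 7 members passing when adjusted over the list alone. Lef1 and Tcf7, transcription factors of naive T cells, differed by -1.10 ± 0.40 and -1.08 ± 0.45. The cytotoxicity list fell with a mean of -0.64 (adjusted p = 0.000187; adjusted p = 0.454 with an estimated correlation), 1 of 14 members passing when adjusted over the list alone. Its members Nkg7 and Ccl5 differed by -1.11 ± 0.43 and -0.99 ± 0.40. Cytosolic ribosomal protein genes fell with a mean of -0.55 (adjusted p = 0.00113; adjusted p = 0.928 with an estimated correlation). Of its 30 members 0 passed when adjusted over the list alone. Rpl5 differed by -0.67 ± 0.44 and Rps27a by -0.83 ± 0.49. Without HFD+L-NAME replicate 5 the means were -0.52 for the CD4 and naive T cell list and -0.41 for the cytotoxicity list. Without HFD+L-NAME replicate 3 the mean was -0.35 for the ribosomal protein list, and these 3 lists kept their calls.

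The immature neutrophil granule list rose with all 5 tested members above 0, a mean of 1.63 and 3 members past the threshold when adjusted over the list alone. Its adjusted p was 2.54e-19, and it kept the call with an adjusted p = 0.00667 with an estimated correlation. Its scores were lowest in chow replicates 1 and 2 (-1.86 and -2.18), 2 of the libraries with peritoneal macrophage genes. Ngp and Camp were highest of all 16 libraries in HFD+L-NAME replicate 1 (142 and 51.3 TPM), which held peritoneal macrophage genes too. In run 1 alone the list mean was 0.44 and the call was lost (camera adjusted p = 0.317). Ltf (lactoferrin) averaged 14.0 ± 11.9 against 2.39 ± 2.30 TPM, a log2 difference of 2.15 ± 0.57, and Camp, the cathelicidin precursor, differed by 2.14 ± 0.62. The heat shock and HSF1 target list rose with a mean of 0.91 (adjusted p = 1.63e-13; adjusted p = 0.319 with an estimated correlation), 0 of 13 members passing when adjusted over the list alone. Hspa1b and Hspa1a, the inducible Hsp70 genes, differed by 3.11 ± 1.33 and 3.05 ± 1.32, and Hspb1 by 1.54 ± 0.68. The heat shock list score was -2.12 in chow replicate 1 and -2.85 in chow replicate 2, 2 of the libraries with peritoneal macrophage genes, and between 0.16 and 1.18 in the other 3 chow libraries. It was also low, at -1.605, in HFD+L-NAME+NO2-OA replicate 2, a run 2 library without those genes. HFD+L-NAME replicate 1, which held them, was the highest of its group for Hspb1. The mean difference of the heat shock list was 0.36 without chow replicate 2, 0.54 without chow replicate 1 and 1.37 without chow replicate 4. Erythroid genes rose with a mean of 0.91 (adjusted p = 4.12e-11; adjusted p = 0.319 with an estimated correlation), with Hba-a1 at 1.22 ± 0.96 and Hba-a2 at 1.19 ± 0.99, and 0 of 11 members passing when adjusted over the list alone. The erythroid mean was 0.19 without chow replicate 1, 0.51 without chow replicate 3, 0.56 without HFD+L-NAME replicate 3, 0.60 without HFD+L-NAME replicate 1, and 1.45 without chow replicate 4 or HFD+L-NAME replicate 5. Platelet genes rose with a mean of 0.46 (adjusted p = 2.31e-07; adjusted p = 0.405 with an estimated correlation), with Gp9 and P2ry12 both at 0.67, and 0 of 13 members passing when adjusted over the list alone. The platelet mean was -0.07 without HFD+L-NAME replicate 3 (camera adjusted p = 0.174), 0.08 without chow replicate 1, 0.27 without HFD+L-NAME replicate 2, 0.87 without chow replicate 5 and 1.08 without HFD+L-NAME replicate 5.

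The remaining 8 lists that rose were those of monocytes and macrophages (Lyz2, 0.57 ± 0.50), complement and Fc receptors, mature neutrophils, NRF2 targets (Hmox1, 0.53 ± 0.47), nitric oxide and guanylate cyclase, classical monocytes, TGF-beta and extracellular matrix, and the unfolded protein response. Their means lay between -0.09 and 0.30, 0 of their members passed when adjusted over the list alone, and each lost its call with an estimated correlation, the smallest adjusted p being 0.319 and the largest 0.928. Without the 3 libraries under 25% protein-coding TPM the means were -0.03 for the monocyte and macrophage list, -0.12 for the complement and Fc receptor list, -0.12 for the mature neutrophil list and -0.10 for the TGF-beta list, with the opposite sign. Hmox1 lay at -0.105 in run 1 alone, also with the opposite sign. The mean of the unfolded protein response list was negative although its test against all other genes pointed up. Single libraries decided the sign of 6 of these 8 lists. Without chow replicate 3 the means were -0.12 for classical monocytes (camera adjusted p = 0.0530), -0.10 for complement and Fc receptors, -0.06 for NRF2 targets, -0.20 for TGF-beta and -0.01 for mature neutrophils. Without chow replicate 1 the mature neutrophil mean was -0.27 (adjusted p = 0.827) and that of the unfolded protein response 0.02. The unfolded protein response lay at 0.07 without HFD+L-NAME replicate 3 and 0.02 without replicate 5 of that group, NRF2 targets at -0.01 without its replicate 4, and TGF-beta at -0.07, -0.02 and -0.12 without its replicates 1, 2 and 4. The monocyte and macrophage mean was 0.02 without chow replicate 3, and that of nitric oxide and guanylate cyclase 0.10 without HFD+L-NAME replicate 3. The TGF-beta and unfolded protein response lists each kept the call in 10 of 16 fits with 1 library left out. Without HFD+L-NAME replicate 5 the mature neutrophil list (adjusted p = 0.150) and the complement and Fc receptor list (adjusted p = 0.0502) lost theirs.

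The test across all 16365 genes called 0 genes up and 1 down in HFD+L-NAME against chow (limma on log2(TPM + 1), adjusted p under 0.05). The gene was Gm23054 (ENSMUSG00000064738), a small nuclear RNA model outside the rule for named genes and chosen after its values were seen. It fell by 4.09 ± 0.61 (SE) on the log2 scale with an adjusted p = 0.00880, from 31.8 ± 14.8 TPM in chow to 3.30 ± 7.38 TPM. The size of this log2 difference depends on the added 1 TPM, as most HFD+L-NAME libraries held 0 reads. Gm23054 held from 2 to 6 recovered reads per chow library and reads in 1 of 5 HFD+L-NAME libraries. With any of HFD+L-NAME replicates 2, 3, 4 or 5 left out, 0 genes were called. Igha (ENSMUSG00000095079), the constant region of immunoglobulin A, had the smallest unadjusted p among the genes named by the rule, at 4.27 ± 2.26 against 20.6 ± 13.5 TPM (-1.97 ± 0.46, adjusted p = 0.817). HFD+L-NAME replicate 5 lay lowest of its group for Igha, at 0.561 on the log2(TPM + 1) scale (others 2.396 to 2.877). Dapl1, Cd96 and the metal-binding Mt2 were among the other genes of smallest unadjusted p named by the rule, with Mt2 at 8.82 ± 10.8 against 1.13 ± 0.736 TPM. At an unadjusted p under 0.05 stood 479 genes, 31 higher and 448 lower, against 818 expected by chance, and limma-voom on the recovered reads called 0 genes. The median log2 difference of all tested genes was -0.29, and 0.03 after rescaling by the median of ratios. Relative to the median of all genes, the T cell list lay at -0.72, the NK cell list at -0.70 and the immature neutrophil granule list at 1.92.

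By an exact two-sided permutation test of the list scores, which here cannot give a p below 0.00794, the immature neutrophil granule list had p = 0.0397, the T cell list p = 0.0476 and the NK cell list p = 0.0952. Of the 45 lists, 3 had an exact p under 0.05, and after adjustment of these exact p-values 0 passed (smallest adjusted p = 0.714). Among the 3 chow and 3 HFD+L-NAME libraries of run 1, which hold no peritoneal macrophage genes, the means were -0.31 for the T cell list (camera adjusted p = 0.000683), -0.42 for the NK cell list (adjusted p = 2.54e-05) and 0.44 for the immature neutrophil granule list (adjusted p = 0.317). They were -0.02 for the heat shock list (adjusted p = 0.309), 0.05 for the ribosomal protein list (adjusted p = 0.425) and -0.85 for the mature neutrophil list (adjusted p = 2.26e-08), the last 3 with the opposite sign. The CD4 and naive T cell list lay at -0.15 there (adjusted p = 0.134), the CD8 T cell list at -0.30 (adjusted p = 0.0605) and the erythroid list at 0.42 (adjusted p = 0.644), and 4 of the 18 lists kept their call and direction. In simulated unchanged groups that kept the correlation between genes, the preset test called at least 1 list in 100 of 100 draws, with a median of 10 lists and a highest of 16. These draws set the mean of each gene to 0, which alters the variance trend, so their counts are no limit for the 18 in the data. Of 100 drawn splits of the 10 libraries, the real one included, 6 called as many lists (highest other 20).

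**Figure D3:**
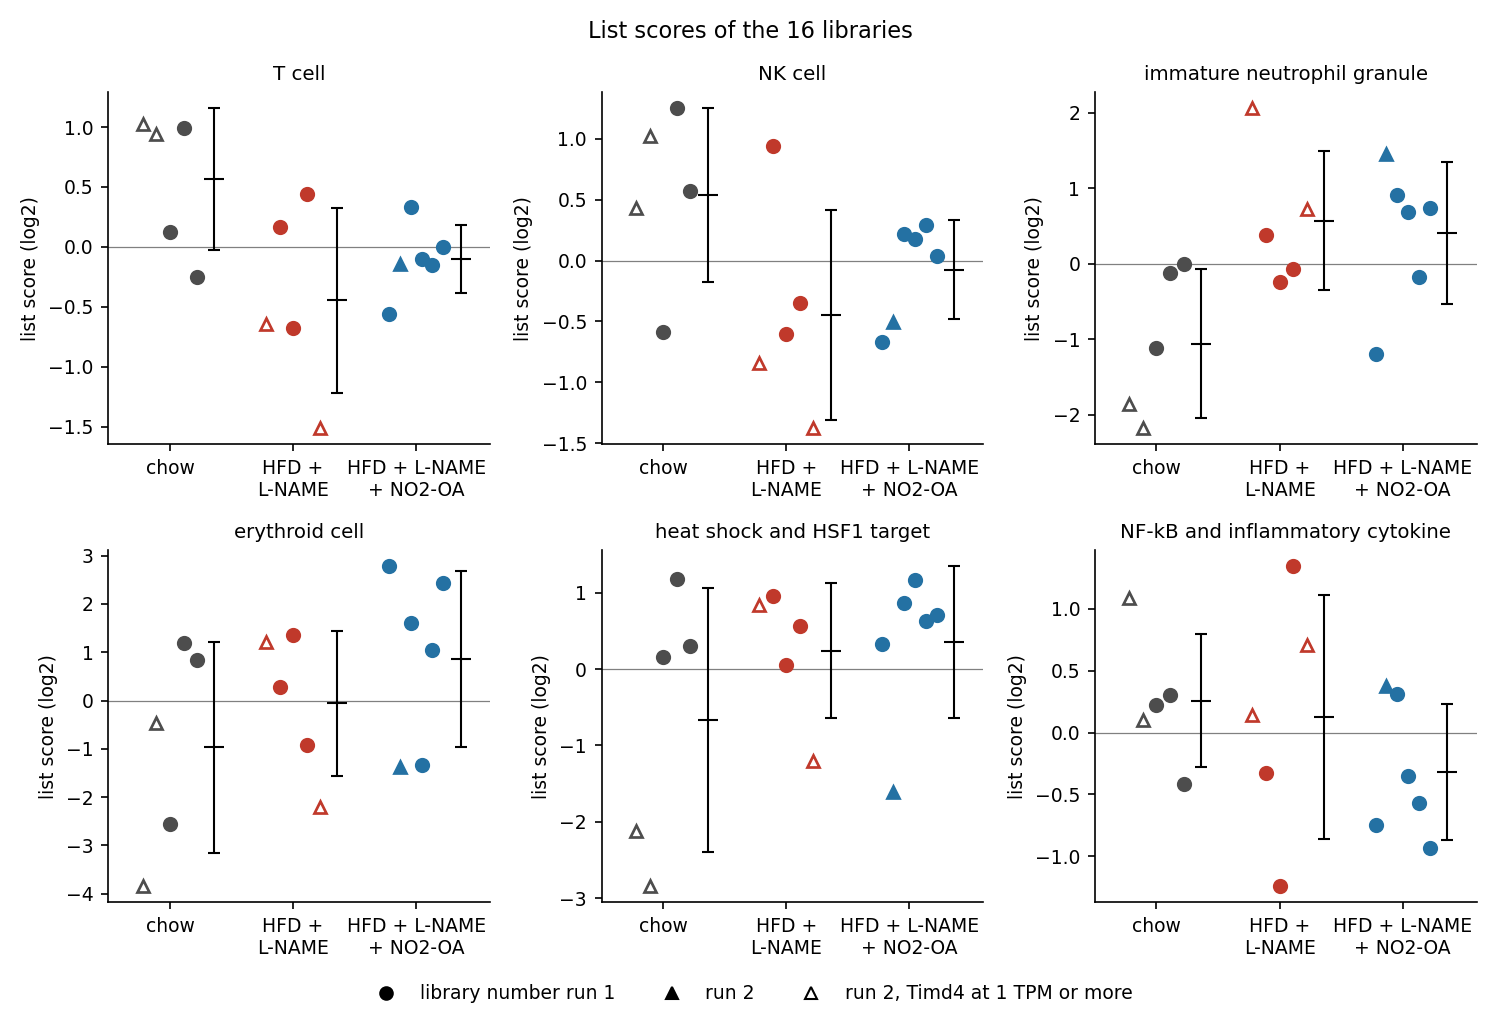
Scores (mean over members of log2(TPM + 1), centred on the mean of all 16 libraries) of 6 gene lists per library, by group, with black marks for the mean ± SD; triangles mark run 2 and open triangles libraries with peritoneal macrophage genes. The T cell score averaged -0.45 in HFD+L-NAME and 0.57 in chow, and the immature neutrophil granule score 0.57 and -1.06.

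The comparison of HFD+L-NAME+NO2-OA with HFD+L-NAME asks what the last 4 weeks of NO2-OA added. Of the 13 gene lists that passed here, each moved by over 1.5-fold or turned when 1 library was left out, and 9 lay closest to 0 without HFD+L-NAME replicate 4 or 5. The 4 genes below did not pass the test over all genes (each adjusted p = 1.00). Cxcl2 (ENSMUSG00000058427), a neutrophil-attracting chemokine, averaged 18.5 ± 25.8 TPM (SD, n = 6) against 95.7 ± 103 TPM (n = 5), a log2 difference of -1.83 ± 0.87 (SE). Ptgs2 (ENSMUSG00000032487), the inducible cyclooxygenase, averaged 3.04 ± 2.48 against 9.11 ± 6.73 TPM (-1.23 ± 0.50), and Ltc4s (ENSMUSG00000020377), leukotriene C4 synthase, 2.02 ± 1.49 against 9.53 ± 8.08 TPM (-1.35 ± 0.61). The interferon-induced gene Rsad2 (ENSMUSG00000020641) averaged 154 ± 120 against 58.8 ± 57.6 TPM (1.36 ± 0.87). In the 4 libraries with peritoneal macrophage genes, 2 of them HFD+L-NAME and 0 treated, Ltc4s lay between 11.3 and 19.5 TPM against at most 12.1 TPM in the other 12. There Cxcl2 lay between 46.2 and 241 TPM against at most 160, and Ptgs2 between 2.40 and 18.04 TPM against at most 10.1.

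The NF-kB and inflammatory cytokine list fell in treated mice with a mean of -0.44, 12 of its 19 members below 0 and 0 past the threshold when adjusted over the list alone. Its adjusted p was 3.1e-06, and the adjusted p = 0.896 with an estimated correlation, a value shared by all 13 lists that passed here. Its mean was -0.14 without HFD+L-NAME replicate 4 (camera adjusted p = 0.0169) and -0.79 without replicate 3 of that group, and the call was lost without its replicate 5 (-0.30, adjusted p = 0.500). Il1a, interleukin-1 alpha, differed by -1.11 ± 0.54, and lay between 1.87 and 14.7 TPM in the 4 libraries with peritoneal macrophage genes against at most 2.10 TPM elsewhere. The immediate early list fell with a mean of -0.44 (adjusted p = 1.98e-06; adjusted p = 0.896 with an estimated correlation), with Fos at -1.06 ± 0.73, Ier3 at -0.81 ± 0.56 and Egr2 at -0.64 ± 0.44. The immediate early mean was -0.01 without HFD+L-NAME replicate 4 (adjusted p = 0.0471) and -0.79 without replicate 3, and the call was lost without replicate 5 (-0.37, adjusted p = 0.171). Platelet genes fell with a mean of -0.53 (adjusted p = 0.000374; adjusted p = 0.896 with an estimated correlation), with Pf4 at -0.69 ± 0.83 and Tubb1 at -0.66 ± 0.85. Without HFD+L-NAME+NO2-OA replicate 2, Pf4 and Tubb1 lay at 0.15 and 0.18 and the platelet mean at 0.26 (adjusted p = 0.819). That mean was 0.00 without HFD+L-NAME replicate 3 (adjusted p = 0.782), -0.34 without HFD+L-NAME replicate 2, -0.94 without HFD+L-NAME+NO2-OA replicate 5 and -1.14 without HFD+L-NAME replicate 5. The glycolysis list (mean -0.15; Gapdh, -0.42 ± 0.34), the monocyte and macrophage list (mean -0.23) and the NRF2 target list (mean -0.13) fell as well, with an adjusted p = 0.896 each with an estimated correlation. Without HFD+L-NAME+NO2-OA replicate 2 glycolysis lay at 0.00 (adjusted p = 0.0659) and NRF2 targets at 0.06 (adjusted p = 0.172). The monocyte and macrophage list lay at -0.08 without HFD+L-NAME replicate 1 (adjusted p = 0.373), at -0.12 without HFD+L-NAME+NO2-OA replicate 6 (adjusted p = 0.294), and lost its call without HFD+L-NAME replicate 5 (adjusted p = 0.910). Without HFD+L-NAME replicate 3 the glycolysis list (adjusted p = 0.357) and the NRF2 target list (adjusted p = 0.800) lost theirs, and the monocyte and macrophage mean was -0.50. Calls were also lost without HFD+L-NAME+NO2-OA replicate 4 (monocytes and macrophages, adjusted p = 0.0706, and NRF2 targets, 0.0635), replicate 5 (monocytes and macrophages, 0.0775) and replicate 6 (NRF2 targets, 0.0820). Without HFD+L-NAME replicate 5 the glycolysis mean was -0.37 and the NRF2 target mean -0.35.

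Erythroid genes rose in treated mice with a mean of 0.92 and all 11 members above 0 (adjusted p = 0.000374; adjusted p = 0.896 with an estimated correlation), with Slc4a1, the anion exchanger of red cells, at 1.20 ± 0.94. The haemoglobin share of these libraries reached 30.7%. The erythroid mean was 0.38 without HFD+L-NAME replicate 5 and 0.61 without HFD+L-NAME+NO2-OA replicate 6, and the call was lost without HFD+L-NAME+NO2-OA replicate 1 (0.54, adjusted p = 0.280) or HFD+L-NAME replicate 4 (0.70, adjusted p = 0.588). Interferon-stimulated genes rose with a mean of 0.32 and 23 of 25 members above 0 (adjusted p = 0.001; adjusted p = 0.896 with an estimated correlation), with Oas2 at 0.57 ± 0.35. The CD4 and naive T cell list rose with a mean of 0.51 and 7 of 7 members above 0 (adjusted p = 0.001; adjusted p = 0.896 with an estimated correlation), with Il7r, the interleukin-7 receptor, at 0.76 ± 0.45 and Tcf7 at 0.66 ± 0.43. The T cell list (mean 0.34; Trac, 0.65 ± 0.43), the NK cell list (mean 0.37; Klrd1, 0.59 ± 0.41), the regulatory T cell list (mean 0.33; Foxp3, 0.40 ± 0.27) and the cGAS-STING list (mean 0.30) rose too, with an adjusted p = 0.896 each with an estimated correlation. Much of these 6 differences came from HFD+L-NAME replicate 5, in which protein-coding genes took 15.1% of TPM. Without it the means were 0.04 for the interferon-stimulated list (adjusted p = 0.0607), 0.17 for the CD4 and naive T cell list (adjusted p = 0.0368), 0.08 for the T cell list (adjusted p = 0.0768), 0.14 for the NK cell list (adjusted p = 0.0262), 0.13 for the regulatory T cell list (adjusted p = 0.0607) and 0.09 for the cGAS-STING list (adjusted p = 0.107). The T cell mean was 0.56 without HFD+L-NAME replicate 4, the NK cell mean 0.72 without HFD+L-NAME replicate 2, and the interferon-stimulated mean 0.54 and 0.20 without HFD+L-NAME+NO2-OA replicates 2 and 5. The cGAS-STING list kept its call in 6 of 16 fits with 1 library left out. Other libraries that ended a call were HFD+L-NAME replicate 1 for T cells (0.29, adjusted p = 0.0891) and NK cells (0.27, adjusted p = 0.137), HFD+L-NAME replicate 4 for NK cells (0.40, adjusted p = 0.178) and regulatory T cells (0.41, adjusted p = 0.138), and HFD+L-NAME+NO2-OA replicate 2 for T cells (0.35, adjusted p = 0.174) and regulatory T cells (0.36, adjusted p = 0.179). Among the 3 HFD+L-NAME and 5 treated libraries of run 1, the mean was -0.07 for the T cell list, 0.13 for the monocyte and macrophage list, both with the opposite sign, and 0.02 for the NK cell list.

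The test called 1 gene up and 0 down. The gene was Gm25131 (ENSMUSG00000064587), a small nuclear RNA model outside the rule for named genes and chosen after its values were seen, at 84.5 ± 24.9 TPM in treated mice and listed at 0 in all 5 HFD+L-NAME libraries. Its fitted log2 difference was 6.37 ± 0.96 (adjusted p = 0.00952), which depends on the pseudocount, and it held from 1 to 3 recovered reads in the 6 treated libraries and from 0 to 3 in chow. With HFD+L-NAME replicate 3, 4 or 5 left out 0 genes were called. Among the genes with the smallest unadjusted p, Pmp22, a myelin and growth arrest gene, averaged 2.03 ± 1.18 against 7.11 ± 3.80 TPM (-1.40 ± 0.41), and Ccrl2, an atypical chemokine receptor, 4.38 ± 3.06 against 20.3 ± 19.9 TPM (-1.52 ± 0.56). In the 4 libraries with peritoneal macrophage genes, Pmp22 lay between 6.74 and 11.35 TPM against at most 9.28 TPM in the other 12. Ccrl2 lay there between 8.38 and 50.9 TPM against at most 28.3 TPM. Alox15 averaged 0.183 ± 0.194 against 69.9 ± 95.2 TPM (-2.99 ± 1.23), Slpi, a protease inhibitor, 28.2 ± 19.7 against 169 ± 179 TPM (-1.81 ± 0.74), and the chemokine Cxcl1 0.162 ± 0.396 against 16.4 ± 31.0 TPM (-2.03 ± 0.86). Alox15, Slpi and Cxcl1, and also C3ar1 (-1.09 ± 0.42), had their 4 highest values in the 4 libraries with peritoneal macrophage genes, 2 of which are HFD+L-NAME and 0 treated. Higher in treated mice were Vcan, the proteoglycan versican (14.4 ± 8.14 against 6.81 ± 5.25 TPM, 1.14 ± 0.50), Igha (0.98 ± 0.44), the interferon-induced GTPase Tgtp1 (0.88 ± 0.35) and Tnfsf8, the CD30 ligand (0.88 ± 0.38). For Igha, HFD+L-NAME replicate 5 lay lowest of its group, at 0.561 on the log2(TPM + 1) scale (others 2.396 to 2.877).

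In this comparison 155 genes had an unadjusted p under 0.05, 79 higher and 76 lower, against 818 expected by chance, and limma-voom called 0. The median log2 difference of all tested genes was 0.08, and -0.04 after rescaling by the median of ratios. The smallest exact p among the 45 lists was 0.165, where 0.00216 is the smallest possible. Without the 4 libraries that hold peritoneal macrophage genes camera called 8 lists, and 4 of the 13 lists above kept their call and direction.

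The comparison of HFD+L-NAME+NO2-OA with chow asks whether treated mice differ from control mice. Immature neutrophil granule genes, classical monocyte genes and erythroid genes lay higher and T cell genes lower in treated mice, again with no gene past the test over all genes (each adjusted p = 0.977). Ngp averaged 48.7 ± 36.0 TPM (SD, n = 6) against 11.1 ± 9.99 TPM (n = 5), a log2 difference of 2.27 ± 0.70 (SE). Vcan averaged 14.4 ± 8.14 against 4.16 ± 4.77 TPM (1.84 ± 0.50), with 6 of 6 libraries above the chow median. Alas2 (ENSMUSG00000025270), the first enzyme of haem synthesis in red cells, averaged 663 ± 605 against 184 ± 180 TPM (2.11 ± 0.96). Trbc2 (ENSMUSG00000076498), the constant region of the T cell receptor beta chain, averaged 107 ± 32.0 against 213 ± 92.8 TPM (-0.90 ± 0.41), with 0 of 6 libraries above the chow median.

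The erythroid list rose with a mean of 1.83 and all 11 members above 0, of which 0 passed when adjusted over the list alone. Its adjusted p was 1.92e-28, with an adjusted p = 0.0611 with an estimated correlation, and without chow replicate 1 its mean was 1.11. Haemoglobin genes took from 1.10% to 30.7% of TPM in the treated libraries and from 0.141% to 7.67% in chow. The immature neutrophil granule list rose with a mean of 1.46, 5 of 5 members above 0 and 3 past the threshold when adjusted over the list alone (adjusted p = 5.86e-19), and it kept the call with an adjusted p = 0.00782 with an estimated correlation. Ltf differed by 1.92 ± 0.55 and Camp by 1.78 ± 0.60. The classical monocyte list rose with a mean of 0.58 and 1 of 8 members past the threshold when adjusted over the list alone (adjusted p = 6.9e-09; adjusted p = 0.164 with an estimated correlation), with Chil3, a chitinase-like protein, at 1.58 ± 0.60. Without chow replicate 3, whose score was -1.83, its mean was 0.20. The heat shock list rose with a mean of 1.02 (adjusted p = 5.67e-17; adjusted p = 0.206 with an estimated correlation), with Hspa1b at 3.26 ± 1.28 and Hspa1a at 3.20 ± 1.26. Without the 4 libraries that hold peritoneal macrophage genes, Hspa1b lay at -0.07 and Hspa1a at -0.04. That fit kept HFD+L-NAME+NO2-OA replicate 2, the lowest of its group for both genes. With 1 library left out, the mean of the list was 0.47 without chow replicate 2 and 0.65 without chow replicate 1. Interferon-stimulated genes rose with a mean of 0.21 (adjusted p = 8e-08; adjusted p = 0.738 with an estimated correlation), with Rsad2 at 2.01 ± 0.87 and Isg15 at 1.22 ± 0.76. Their mean was 0.01 without chow replicate 3, 0.36 without chow replicate 4, and 0.43, 0.13 and 0.09 without HFD+L-NAME+NO2-OA replicates 2, 3 and 5. Isg15 lay at -0.225 with erythroid, platelet and neutrophil scores as covariates, and at -1.1 in run 2, which holds 1 treated library. The 5 further lists that rose, those of mature neutrophils, complement and Fc receptors, monocytes and macrophages, nitric oxide and guanylate cyclase, and mitochondrially encoded genes, had means between -0.02 and 0.15, and each had an adjusted p of at least 0.738 with an estimated correlation. With the values rescaled over protein-coding genes alone, the means were -0.29 for complement and Fc receptors, -0.06 for monocytes and macrophages and -0.09 for nitric oxide and guanylate cyclase. The mean of the mitochondrially encoded list was negative while its test pointed up. Single libraries turned the sign of each of these 5 means: without chow replicate 1 it was -0.42 for mature neutrophils (camera adjusted p = 0.170) and -0.10 for nitric oxide and guanylate cyclase (adjusted p = 0.561), without chow replicate 3 -0.26 for complement and Fc receptors (adjusted p = 0.188) and -0.21 for monocytes and macrophages (adjusted p = 0.191), and without HFD+L-NAME+NO2-OA replicate 2 0.15 for mitochondrially encoded genes (adjusted p = 0.0477). They kept their calls in 8 to 14 of 16 fits with 1 library left out.

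The T cell list fell with a mean of -0.67 and all 11 members below 0 (adjusted p = 1.06e-06; adjusted p = 0.726 with an estimated correlation), with Cd3g at -0.84 ± 0.37. The NK cell list fell with a mean of -0.61 (adjusted p = 8.8e-05; adjusted p = 0.738 with an estimated correlation), with Klra4 at -1.02 ± 0.42. The CD8 T cell list fell with a mean of -0.61 (adjusted p = 0.00858; adjusted p = 0.738 with an estimated correlation), with Cd8b1 at -1.01 ± 0.42 and Eomes, a transcription factor of memory and NK cells, at -0.71 ± 0.31. The cytotoxicity list (mean -0.44; Gzma, -1.02 ± 0.48) and the cytosolic ribosomal protein list (mean -0.55; Rpl3, -0.65 ± 0.43) fell with an adjusted p = 0.835 each with an estimated correlation. The NF-kB list (mean -0.58; Cxcl2, -2.05 ± 0.87) and the immediate early list (mean -0.60; Egr1, -1.23 ± 0.62) fell with an adjusted p = 0.935 and an adjusted p = 0.942 with an estimated correlation. In these 7 lists 0 members passed when adjusted over the list alone. Without chow replicate 1 the immediate early mean was -0.16 (camera adjusted p = 0.817) and the NF-kB mean -0.37 (adjusted p = 0.170). Both lists also lost the call without chow replicate 3 (-0.46, adjusted p = 0.601, and -0.59, adjusted p = 0.548) and without HFD+L-NAME+NO2-OA replicate 4, 5 or 6 (adjusted p from 0.0706 to 0.177). Without chow replicate 4 the CD8 T cell list lay at -0.47 (adjusted p = 0.0971) and the cytotoxicity list at -0.30 (adjusted p = 0.254). The cytotoxicity list also lost its call without chow replicate 5 (adjusted p = 0.0702) and HFD+L-NAME+NO2-OA replicate 4 (adjusted p = 0.0820).

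**Figure D4:**
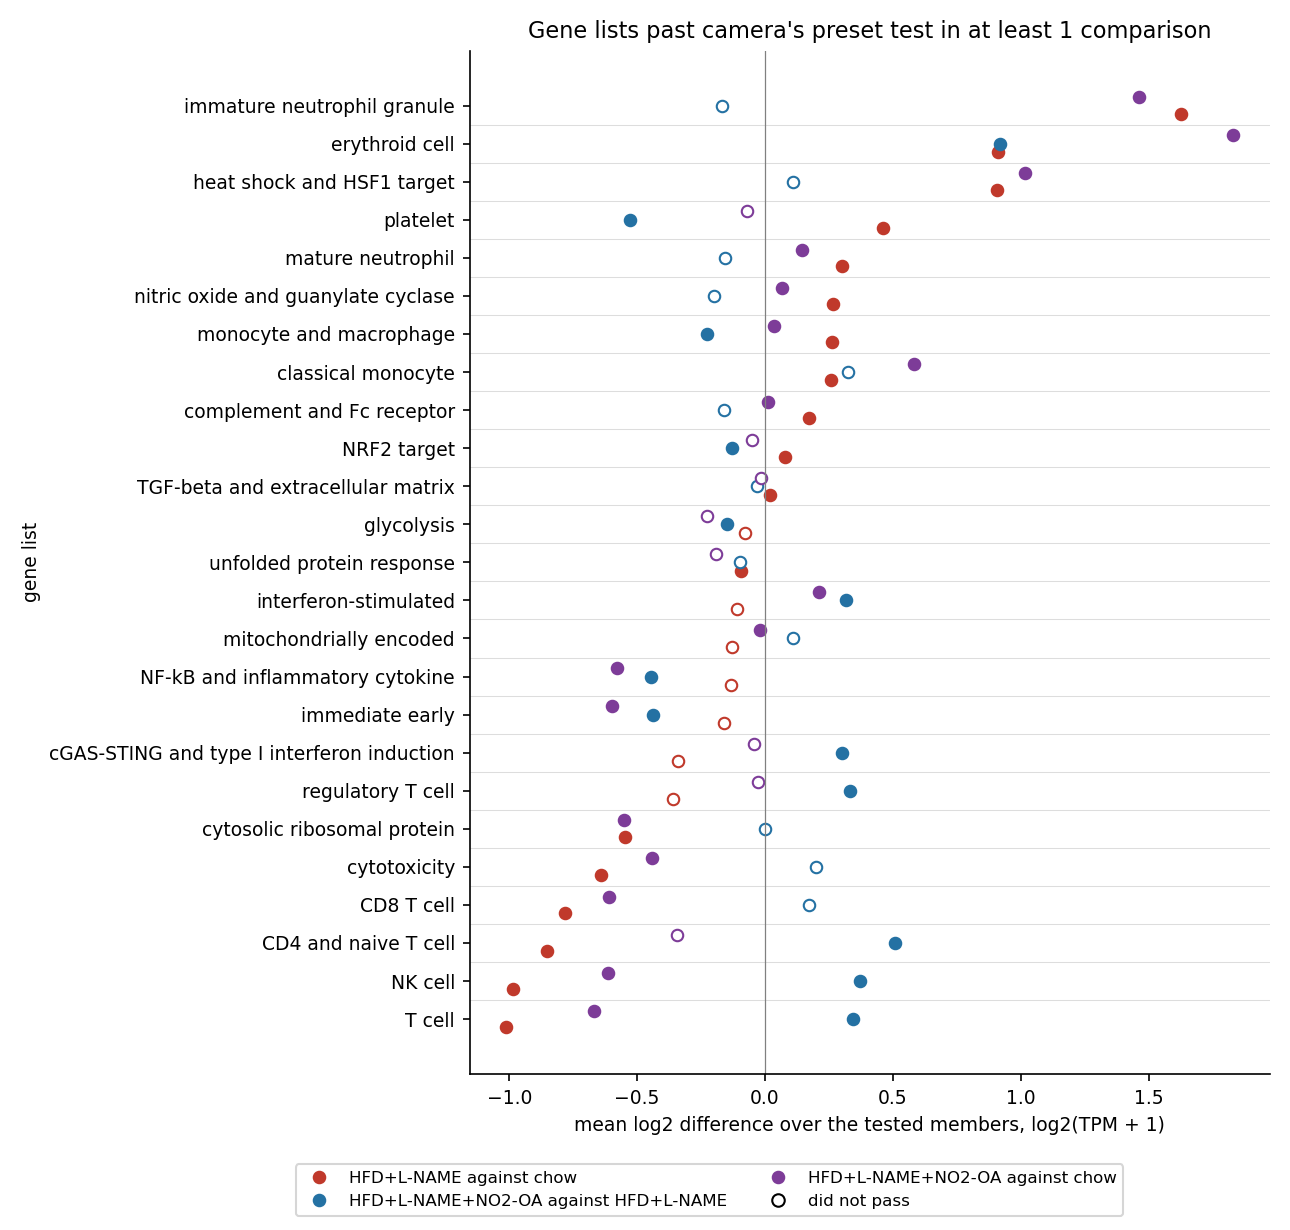
Mean difference on the log2(TPM + 1) scale over the tested members of each of the 25 gene lists that passed camera with its preset correlation in at least 1 comparison; filled points passed in that comparison and open points did not. The T cell list lay at -1.01 for HFD+L-NAME against chow, 0.34 for HFD+L-NAME+NO2-OA against HFD+L-NAME and -0.67 for HFD+L-NAME+NO2-OA against chow.

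The test called 0 genes up and 0 down in HFD+L-NAME+NO2-OA against chow, limma-voom also called 0, and 458 genes had an unadjusted p under 0.05, 70 higher and 388 lower, against 818 expected by chance. Further genes of the set with the smallest unadjusted p were Ms4a6d (9.51 ± 4.72 against 3.55 ± 2.59 TPM, 1.25 ± 0.40), the mitotic ubiquitin enzyme Ube2c (1.63 ± 0.64), the aryl hydrocarbon receptor Ahr (1.02 ± 0.41), Pmp22 (-1.02 ± 0.41), Bcl2a1d, a survival factor of the Bcl2 family (-0.83 ± 0.33), and the mitochondrial nuclease Endog (-0.91 ± 0.32). Pmp22 lay at 6.74 TPM or more in the 4 libraries with peritoneal macrophage genes, 2 of them chow and 0 treated. The median log2 difference of all tested genes was -0.20, and -0.01 after rescaling by the median of ratios. By the exact permutation test the immature neutrophil granule list had p = 0.0519, the T cell list p = 0.0498 and the plasmacytoid dendritic cell list, which did not pass camera, p = 0.0303. The last 2 were the only lists with an exact p under 0.05, so the erythroid and classical monocyte lists had none. After adjustment of the exact p-values 0 of 45 lists passed (smallest adjusted p = 0.646). Among the 3 chow and 5 treated libraries of run 1, the mean was 1.49 for the erythroid list (camera adjusted p = 1.28e-10) and 0.61 for the immature neutrophil granule list (adjusted p = 0.00416). It was -0.38 there for the T cell list (adjusted p = 9.37e-06) and 0.20 for the heat shock list (adjusted p = 0.566). The mature neutrophil list lay at -0.52, with the opposite sign. These p-values come from camera with its preset correlation. That test called lists in 100 of 100 unchanged draws simulated for HFD+L-NAME against chow, so these p-values alone do not show a difference.

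Whether expression under NO2-OA lay back toward chow was asked by relating the log2 differences of HFD+L-NAME against chow to those of HFD+L-NAME+NO2-OA against HFD+L-NAME across the 16365 tested genes, which are not independent replicates. Pearson's r was -0.519, the covariance -0.046, and 74.2% of genes had opposite signs. The 1 gene called in the first comparison, Gm23054, had the opposite sign in the second (3.10 ± 0.59, adjusted p = 0.143). The HFD+L-NAME libraries enter both differences with opposite sign, and in 100 simulated sets of unchanged groups that share them r averaged -0.519 ± 0.245 (SD), with 53 sets at least as negative as the data. In these sets the covariance averaged -0.067 ± 0.054, with 60 at least as negative. The share of opposite signs averaged 67.1% ± 18.3, with 45 sets at least as high as the data. When the HFD+L-NAME libraries were split so that the differences shared none, over 20 splits, r averaged 0.134 (from -0.083 to 0.446) and was negative in 2 of 20. The share of opposite signs among the 479 genes at an unadjusted p under 0.05 was 87.3%, against 89.0% ± 16.1 in the simulated sets. The p-values of those sets come from genes with means set to 0, and so from another variance trend. A return toward chow was thus not detectable beyond what the shared libraries give, and within run 1 r was -0.563 with the libraries shared.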

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

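All tests in this part except the counts of further macrophage markers and of mast cell genes were chosen only after the result was seen. In 357 groups of 5 or 6 libraries, 21 held a library far from the others, where chance flags about 1 in 20 groups, about 18 here. On the log2(TPM + 1) scale, HFD+L-NAME+NO2-OA replicate 2 stood lowest in its group for Hspa1a at 7.697 (others 10.94 to 11.73), Hspa1b at 7.951 (11.2 to 11.99), Hspb1 at 0.8596 (3.351 to 4.587), Pf4 at 5.781 (9.837 to 11.88), Tubb1 at 5.303 (9.411 to 11.62) and Pmp22 at 0 (1.465 to 2.093), and highest for Cxcl1 at 0.979 (others 0). The same library stood lowest for the scores of the heat shock list at -1.605 (0.3255 to 1.174), the PPAR target list at -0.8304 (-0.06998 to 0.3346) and the non-classical monocyte list at -1.008 (-0.06097 to 0.2428). HFD+L-NAME replicate 5 stood lowest for Igha at 0.5612 (2.396 to 2.877), for Jchain, the joining chain of immunoglobulins, at 0.2038 (0.7855 to 1.021), and for the share of protein-coding TPM at 15.08% (40.74% to 49.8%). Chow replicate 3 stood lowest for that share at 22.13% (39.15% to 45.0%), the classical monocyte score at -1.833 (-0.2162 to 0.3661) and the glycolysis score at -0.533 (0.2013 to 0.3206). HFD+L-NAME replicate 1 stood highest for Gm23054 at 4.13 (others 0) and Hspb1 at 5.306 (3.71 to 3.891), and HFD+L-NAME replicate 3 lowest for the monocyte and macrophage score at -0.9098 (0.2904 to 0.7385). HFD+L-NAME+NO2-OA replicate 3 stood highest for Ahr at 4.415 (3.345 to 3.56), and replicate 1 lowest for Gzma at 2.993 (4.239 to 4.777).

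The 2 genes called, Gm23054 and Gm25131, are small nuclear RNA models. The highest recovered read number of either gene in any library was 6, where steps of single reads in very short genes would keep it under 10. A read stood for 3.45 to 12.4 TPM of Gm23054 and 22.4 to 80.9 TPM of Gm25131, so these calls may rest on the presence or absence of single reads. Of 100 drawn splits of the 10 libraries, 27 called as many genes as HFD+L-NAME against chow (1; highest of the other splits 22), and 12 of 100 as many as HFD+L-NAME+NO2-OA against HFD+L-NAME (1; highest other 601), so chance could not be excluded for either count. The split with 601 genes set HFD+L-NAME replicates 1, 4 and 5 and treated replicates 1, 2 and 3 apart, and a split with 459 genes differed from it only in the side of HFD+L-NAME replicate 1. These 2 splits were picked for their high counts, and whether a structure of the samples lies behind them stays open. All 3 run 2 libraries lay on 1 side in 22 of the other splits, of which the second highest called 1 gene. Both libraries under 25% protein-coding TPM lay on 1 side in 52, with a median of 0 genes. The counts of 601 and 459 were both among these 52, and in the remaining 47 splits the highest count was 1 gene. So neither arrangement by itself was enough for a high count, but both high counts had the low protein-coding libraries on 1 side. For HFD+L-NAME against chow, all run 2 libraries lay on 1 side in 5 of the other splits. Each of these 5 called a gene (median 3, highest 11), against 21 of the remaining 94 (median 0, highest 22).

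Resident peritoneal macrophage genes stood high in chow replicates 1 and 2 and HFD+L-NAME replicates 1 and 5. A candidate explanation is cells of the peritoneal cavity among the blood cells. All 9 markers whose values were seen before they were listed had their 4 highest values there, which restates the observation and is no test of it. Of 6 further markers unseen before the test, 4 had their 4 highest values there too (Rarb, Tgfb2, Marco and Ednrb, not Hgf and Dnah12). The abundant genes Fn1 (235 to 390 TPM against at most 94.0), Slpi (146 to 380 against at most 74.4) and C1qb (50.1 to 122 against at most 0.621) were high in the same libraries, and the labels name Ficoll separation but no sort that would remove such cells. Mast cells of the peritoneal cavity carried along cannot be told apart from their absence. The pattern was seen in 0 of 3 of their genes, but Tpsb2 and Mcpt4 held at most 1 recovered read, in HFD+L-NAME replicate 1, and Cma1 at most 2.88 TPM (chow replicate 2), against at most 2.12 TPM outside the 4 libraries. These genes lay in 4 of 5 run 2 libraries and 0 of 11 of run 1 (Fisher's exact two-sided p = 0.00275), while treatment with NO2-OA (0 of 6 libraries against 4 of 10, Fisher's exact two-sided p = 0.234) cannot be told apart from chance with so few libraries, and whether collection or the cells themselves differ between runs stays open.

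Lower T cell and higher immature neutrophil granule genes in HFD+L-NAME against chow were weighed against 3 explanations. The run of library numbers was not among them. Each group held 3 libraries of run 1 and 2 of run 2, and all 4 of run 2 held peritoneal macrophage genes. A single scale factor per library as the whole cause was argued against. Median-of-ratios rescaling, which moved the median of all genes from -0.29 to 0.03, left the T cell list at -0.63 (exact two-sided permutation p = 0.0238) and the immature neutrophil granule list at 1.88 (exact p = 0.0317). The difference of the 2 scores, in which such a factor cancels only for genes well above the added 1 TPM (Ltf averaged 2.39 TPM in chow), was 2.64 higher in HFD+L-NAME (exact p = 0.0238), with 5 of 5 libraries above the chow median, 0.75 in run 1 and 5.48 in run 2. These p-values are not adjusted, and the 2 lists are the highest and the lowest of 45: a range over all lists as wide as this came in a share of 0.190 of the splits of the 10 libraries (exact permutation p = 0.190). So chance is not excluded for the pattern itself. Dilution of all lymphocytes by other cells (T cell minus B cell score -0.60, exact p = 0.151) and more neutrophils of every age (immature minus mature score 1.33, exact p = 0.0794) cannot be told apart from a change in these cells, as both exact p-values lay above 0.05 with n = 5 per group. An effect of diet and L-NAME itself stays open and untested against them. Of 100 drawn splits, 6 called as many lists as the real one (18; highest other 20), so chance could not be excluded.

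For the other counts, 11 of 100 splits called as many lists as HFD+L-NAME+NO2-OA against HFD+L-NAME (13; highest other 18), and chance could not be excluded. For HFD+L-NAME+NO2-OA against chow, 2 of 100 splits called as many lists (17; highest other 17), a share under 0.05 taken alone. This is 1 of 6 such counts, and another split also reached 17 lists. By fry and by the exact permutation test 0 lists passed (smallest exact adjusted p = 0.646). So chance was excluded neither for this count nor for the lists. The count of 0 genes there was reached by 100 of 100 splits (highest other 1) and says nothing against chance.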

How the results depend on the processing

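The tests added after the result was seen are protein-coding genes alone, voom, the sets without low protein-coding or peritoneal libraries, the 2 library number runs alone and the minimum of 10 recovered reads. Over 36 alternatives per comparison, 2960 of 3071 values of 86 pairs of a named gene and a comparison kept their direction and side of the threshold, 68 passed it (47 with array weights, 21 in run 2 alone), 23 no longer did, all of Gm23054 or Gm25131, and 20 changed direction. Depth limits single genes: 1 read of a 1-kb gene stood for 0.0464 to 0.180 TPM. Except where construction shows it, the cause was not tested.

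For HFD+L-NAME against chow, 1 gene was called. The count was 0 with no filter, median-of-ratios rescaling, quantile normalization, robust variance, protein-coding genes, voom, voom with quality weights, without the 3 libraries under 25% protein-coding TPM, and with at least 10 recovered reads. It was 4 with only the 2 groups compared, 2 without the 4 libraries with peritoneal macrophage genes, 2 in run 1, 104 in run 2, and 4205 with array weights, Gm23054 not among them. These weights did not converge, and HFD+L-NAME replicate 1 had a weight of 15.6 and HFD+L-NAME+NO2-OA replicate 6 one of 5.43. Leave-one-out counts ran from 0 (without HFD+L-NAME replicate 2, 3, 4 or 5) to 2 (without chow replicate 1 or 5, or HFD+L-NAME replicate 1). For HFD+L-NAME+NO2-OA against HFD+L-NAME, 1 gene was called. The count was 0 with median-of-ratios rescaling, quantile normalization, robust variance, marker scores as covariates, protein-coding genes, voom, voom with quality weights, without the 3 low protein-coding libraries and with at least 10 recovered reads. It was 2 with a pseudocount of 0.1 TPM, with the run as covariate and without the 4 peritoneal libraries, 3 in run 1, 46 in run 2 and 1815 with array weights. With no filter it was again 1, but another gene, called down. Leave-one-out counts ran from 0 (without HFD+L-NAME replicate 3, 4 or 5) to 4 (without HFD+L-NAME+NO2-OA replicate 2), with 2 without HFD+L-NAME replicate 1. For HFD+L-NAME+NO2-OA against chow, where limma called 0 genes and 458 had an unadjusted p under 0.05, voom called 0, array weights 34, run 1 1 and run 2 330, and leave-one-out counts ran from 0 to 1 (without HFD+L-NAME+NO2-OA replicate 2). Run 2 holds fewer samples by construction, 2 chow, 2 HFD+L-NAME and 1 treated library, the last assumed to vary like the others.

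Gene lists called numbered 18 for HFD+L-NAME against chow, and 6 without the 4 peritoneal libraries, 5 in run 1, 1 by camera with an estimated correlation, 0 by fry and 0 by the exact permutation test, with 15 to 21 under leave-one-out. For HFD+L-NAME+NO2-OA against HFD+L-NAME they numbered 13, and 7 with marker scores as covariates, 22 with protein-coding genes, 8 without the 4 peritoneal libraries and 0 by each of the estimated correlation, fry and the exact permutation test, with 7 (without HFD+L-NAME replicate 5) to 17 under leave-one-out. For HFD+L-NAME+NO2-OA against chow they numbered 17, and 10 with marker scores as covariates, 1 with an estimated correlation, 0 by fry and 0 by the exact permutation test, with 13 to 18 under leave-one-out. With the replicate block, genes called numbered 1, 1 and 0 and lists 18, 11 and 16 in the 3 comparisons.

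Direction changed as follows. Without the 4 peritoneal libraries, and equally in run 1 alone, HFD+L-NAME against chow gave -0.047 for Hspb1, 0.031 for Rps27a and -0.105 for Hmox1. Without the 4 libraries HFD+L-NAME+NO2-OA against chow gave -0.066 for Hspa1b and -0.041 for Hspa1a. In run 2, HFD+L-NAME against chow gave -0.527 for P2ry12 and -0.150 for Gp9. There HFD+L-NAME+NO2-OA against HFD+L-NAME gave 0.506 for Fos, -0.073 for Rsad2 and -0.132 for Slc4a1, and HFD+L-NAME+NO2-OA against chow gave -1.100 for Isg15. With array weights, HFD+L-NAME+NO2-OA against HFD+L-NAME gave 0.590 for Pf4, 0.411 for Tubb1 and -0.012 for Foxp3. Under leave-one-out it gave from -1.204 for Pf4 and -1.258 for Tubb1 (without HFD+L-NAME replicate 5) to 0.151 and 0.179 (without HFD+L-NAME+NO2-OA replicate 2). With marker scores as covariates, Isg15 lay at -0.225 in HFD+L-NAME+NO2-OA against chow. The relation of log2 differences had r = -0.519, 0.134 with the HFD+L-NAME libraries split so that none was shared, and from -0.703 to -0.523 under the other alternatives, with -0.659 to -0.360 under leave-one-out.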

Other observations

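No tests in this part were chosen only after the result was seen. B cell genes did not pass in any of the 3 comparisons by limma's camera, from which all adjusted p-values of this paragraph come: the mean log2 difference of the 12 tested members was -0.41 in HFD+L-NAME against chow (exact permutation p = 0.468), 0.10 in HFD+L-NAME+NO2-OA against HFD+L-NAME (exact permutation p = 0.833) and -0.32 in HFD+L-NAME+NO2-OA against chow (exact permutation p = 0.528). Cd79a averaged 429 ± 235 TPM in chow (SD, n = 5), 307 ± 126 in HFD+L-NAME (n = 5) and 298 ± 123 in HFD+L-NAME+NO2-OA (n = 6). MHC class II presentation genes had means of -0.45 (adjusted p = 0.456), 0.20 (adjusted p = 0.393) and -0.25 (adjusted p = 0.987) in the same order. Plasmacytoid dendritic cell genes, with 3 tested members, had means of -0.42 (adjusted p = 0.139), 0.02 (adjusted p = 0.888) and -0.40 (adjusted p = 0.0642). Pathways of lipid handling did not pass either. In HFD+L-NAME against chow the mean was -0.16 for PPAR targets (adjusted p = 0.365), -0.31 for LXR targets (adjusted p = 0.728), and -0.25 for cholesterol synthesis (adjusted p = 0.660).

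The 4 lists with too few tested members are given by their most abundant genes. Hdc, the histamine-forming enzyme of basophils and mast cells, averaged 16.8 ± 16.6 TPM in chow (SD, n = 5), 15.8 ± 8.196 in HFD+L-NAME (n = 5) and 10.2 ± 8.12 in HFD+L-NAME+NO2-OA (n = 6). The eosinophil receptor gene Il5ra averaged 7.03 ± 4.41, 6.56 ± 2.91 and 5.22 ± 1.57 TPM. Gata1, from the haematopoietic progenitor list and also a factor of red cell and platelet precursors, averaged 8.79 ± 6.42, 10.2 ± 9.60 and 9.31 ± 6.76 TPM. Vwf, from the endothelial list and also made by platelets, averaged 120 ± 110, 207 ± 200 and 168 ± 145 TPM, and the endothelial receptor Kdr 0.520 ± 0.373, 0.596 ± 0.522 and 0.583 ± 0.310 TPM.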
